A study of Mus musculus with 4 samples.

How the data were processed

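Gene expression was measured with an Affymetrix array in MC3T3-E1 cells, a pre-osteoblast line derived from the calvaria of C57BL/6 mice. Cells received proliferation medium alone or with citalopram, a selective serotonin reuptake inhibitor, at 0.0001 mol per litre (100 µM), and RNA was taken on day 3 or day 7. The 4 arrays are 1 array for each of the 4 groups, so no group has a replicate. Per the labels' protocols, cells were seeded at 50000 per well in 6-well plates, with 3 wells untreated and 3 wells treated, and the culture medium held 1% fetal bovine serum. Per the labels' protocols, total RNA was extracted with Trizol, and 250 ng was turned into biotin-labelled cDNA with a whole-transcript kit. Whether the 3 wells were pooled for an array is not given in the sources used here.

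The values are log2 expression values made by the authors, 1 per feature and array, taken as deposited. The base of the logarithm is inferred from the range, 3.90 to 15.5, and no source used here states it. Partek is the only tool named, per the submitters' processing notes, with no version. The background correction, the normalization and the summarization of probes are not given in the sources used here. A step that equalised the arrays would hide a change shared by most transcripts, and a step that did not would leave shifts between arrays in every difference. The medians of the deposited values were 6.50 for control at day 3, 6.50 for citalopram at day 3, 6.60 for control at day 7 and 6.66 for citalopram at day 7, so the arrays had not been brought to identical distributions over all features. The number of arrays limits the precision of every value.

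Of 35556 features, 21789 carried 1 gene symbol in the platform annotation (61.3%), 1621 carried several and 12146 carried none (34.2%). Genes were named only from features with 1 symbol. Symbols were checked through Entrez numbers against a RefSeq gene table of assembly GRCm38.p6, in which 21698 of the numbers were found and 91 were not, and 0 symbols differed. For each of 19938 genes, the feature with the highest mean over the 4 arrays was kept; 999 genes had more than 1 feature.

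Differences of log2 values were taken between citalopram and control at each day, and between day 7 and day 3 within each treatment. A gene entered a count when the brighter of its 2 arrays reached the 40th percentile of genes on that array, a floor between 5.95 and 6.01. Genes were counted at 2-fold and at 1.5-fold. Because a single pair of arrays gives no spread, no p-value was attached to these differences. Genes changed 1.5-fold the same way at both days were set beside the number that independent lists would share. The mean of the citalopram changes at the 2 days was set beside their difference divided by 2, which carries the same array noise plus any real difference between the days.

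Before the data were examined, 36 gene lists and 10 lists of cell type markers were fixed, with 960 members, of which 895 were measured and the other 65 were not analysed here. The median difference of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A median outside the central 95% of these is said to stand apart, which describes these arrays and is not a test, since random lists hold no co-regulated genes. By chance 2.3 of the 46 lists would stand apart in each comparison, and 184 list comparisons were made in all.

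The tests across genes came from a limma fit (version 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment) with additive terms for treatment and day, on genes above the floor on at least 1 array. This fit leaves 1 residual degree of freedom per gene. Where stated, p-values were instead adjusted over the members of 1 list alone, in each of the 46 lists, with no adjustment across lists. Days stand in for replicates of a treatment and treatments for replicates of a day, so a p-value measures only whether an effect was alike in both pairs of arrays. Nothing in the labels says that the arrays came from more than 1 culture experiment, so the spread may be technical. On simulated values for 12415 genes, limma called 39 of 50 genes given a log2 change of 0.6 (78.0%) and 50 of 50 at a change of 1.0. It also called 21 unchanged genes. The simulated changes were placed only in bright genes and were equal at both days, a setting that favours calls. These shares therefore do not show how many real changes, which can differ between days, limma would miss. Of 300 simulated lists of unchanged genes, 6.0% stood apart, as did 19 of 20 lists of 25 genes shifted by 0.15. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

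Genes named in the text were chosen by a rule fixed before the values were seen. For the parts of the rule on single comparisons, symbols starting with Gm and a digit, LOC, Olfr, Vmn, Mir, Snor or n-R5, ending in Rik, or holding a dot or "-ps" were left out. For both days together the rule takes up to 12 genes per direction, by the smaller of the 2 changes, among genes changed 1.5-fold the same way at both days. At each day and for each time comparison it takes the 6 highest and 6 lowest genes, and for the difference between days the 5 highest and 5 lowest. It takes up to 4 members of each list described, by the absolute mean citalopram change or, for time, by the absolute change in control, and it allows any member of the lists for osteoblast differentiation, cholesterol synthesis and uptake, and serotonin and monoamine handling. A gene or class named outside the rule is said to have been chosen after its values were seen.

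Alternatives were other scalings (quantile normalization, cyclic loess, a common median), other floors, the mean of a gene's features, the mean of a list in place of its median, unmatched random lists, limma with the tested factor alone or with a trend, and each array left out. Quantile normalization over features with 1 symbol, and 2 of the scalings for limma, were added after the data were seen.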

Results

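MC3T3-E1 mouse pre-osteoblasts were profiled on 4 arrays: untreated cells and cells given 100 µM citalopram, each at day 3 and day 7, with 1 array per group. The series asks how exposure to this serotonin reuptake inhibitor bears on osteogenesis, and its stated comparison is citalopram against control. Pairs of arrays correlated with Pearson's r from 0.986 to 0.995 over all features. No group had a replicate, so the error of a difference at a single day cannot be estimated, and the number of arrays limits its precision.

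At day 3, Hmox1, the gene of haem oxygenase 1, was 2.04-fold higher with citalopram (log2 difference 1.03). Serpinb9b, of a family of serine protease inhibitors, was higher by 1.06 on the log2 scale, and Adgrg1, an adhesion G protein-coupled receptor, by 1.03. Efhd1, an EF-hand protein, was higher by 0.96, Atp6v0d2, a subunit of the vacuolar proton pump, by 0.95, and Fabp7, a fatty acid-binding protein, by 0.94. The lowest named genes were 3 histone genes, H3c15 (-1.08), H4c6 (-0.83) and H2ac4 (-0.83), together with Ctsw (cathepsin W, -0.95), the DNA repair factor Slf1 (-0.86) and the centrosome gene Cep192 (-0.82). Histone genes have near-identical copies, so their single values are uncertain, and the features of Cep192 ranged from -0.82 to -0.13 and those of Slf1 from -0.86 to -0.36. Of 12196 genes above the floor, 5 were at least 2-fold higher and 2 at least 2-fold lower, and 61 and 37 passed 1.5-fold. The 2-fold genes outside the naming rule, given here after their values were seen, were Olfr936 (1.04), Olfr1082 (1.04) and Gm24463 (-1.11).

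The antioxidant genes controlled by NRF2 were higher with citalopram at day 3, in 20 of 21 members (median log2 difference 0.20; matched random lists -0.02 to 0.12). Among them were Hmox1, Gstm1, a glutathione transferase (0.67), and Gclc, the catalytic subunit of glutamate-cysteine ligase (0.46). The NRF2 list also stood above its matched range between the 2 untreated arrays, by 0.12 at day 7 against day 3. Genes of cholesterol synthesis and uptake were higher in 19 of 21 (median 0.22), led by Hsd17b7 (0.66) and Srebf2, the transcription factor that drives the pathway (0.47). A further 10 lists stood above the matched range, with medians of 0.11 to 0.18: osteoblast differentiation, mineralisation and phosphate handling, Wnt signalling, BMP and TGF-beta signalling, FGF, IGF and PDGF signalling, immediate early genes, matrix proteases and inhibitors, fatty acid synthesis, vacuolar ATPase, and hypoxia and glycolysis. In these, Pdgfra, a receptor for platelet-derived growth factor, was higher by 0.71, the Wnt co-receptor gene Lrp4 by 0.67 and the Wnt agonist gene Rspo2 by 0.52. Mitosis genes were lower in 38 of 39 (median -0.23; matched range -0.01 to 0.10) and genes of DNA replication and S phase in 27 of 34 (median -0.13). Nuclear-encoded genes of oxidative phosphorylation (median -0.03, 23 of 35 lower), interferon response genes (-0.07, 17 of 27 lower) and endothelial markers (-0.09, 5 of 7 lower) also stood below their matched ranges. Only 1 of the 7 endothelial markers reached the floor, and that list lay within its range by the mean and against unmatched lists. The interferon list had a mean of 0.03, opposite in sign to its median, and only 18 of its 27 members reached the floor on any array. Its highest members were Usp18 (0.80), Ifit1 (0.61) and Ifit3 (0.45). In all, 12 of 46 lists stood above and 5 below, where 2.3 would stand apart by chance.

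**Figure D1:**
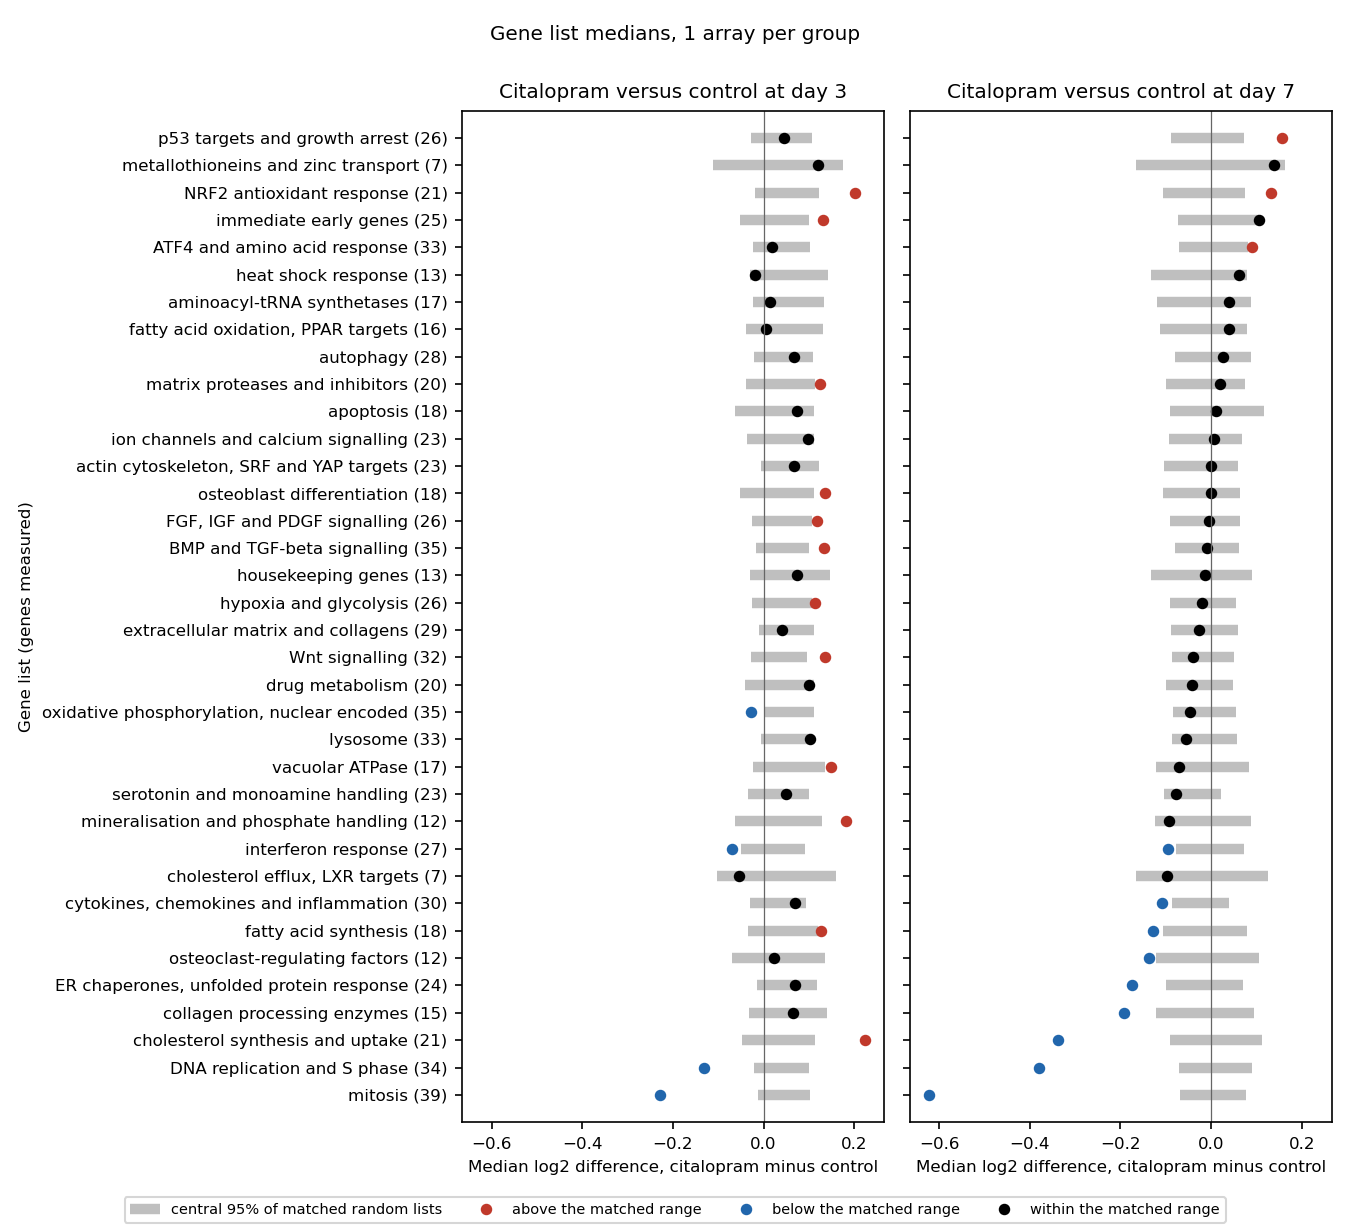
Median log2 difference, citalopram minus control, of each of the 36 gene lists at day 3 (left) and day 7 (right), with the number of genes measured in brackets; grey bars span the central 95% of 10000 random lists matched on expression, and colour marks medians above or below that range. Mitosis lies lowest at both days (-0.23 and -0.62), and cholesterol synthesis and uptake lies above its range at day 3 (0.22) and below it at day 7 (-0.34).

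At day 7, Fosb, a subunit of the AP-1 transcription factor, was 2.59-fold higher with citalopram (log2 difference 1.38). Irs1, insulin receptor substrate 1, was 2.23-fold higher (1.15). Asporin (Aspn, 1.09) and Mest (1.09), an imprinted gene, followed, with Rtl3 (1.04) and the prostaglandin F receptor gene Ptgfr (0.87). Ccl2, a chemokine that attracts monocytes, was lowest (-1.38), then Nppb, which encodes B-type natriuretic peptide (-1.17), the mitotic regulator Pimreg (-1.13), Cenpa, the centromeric histone variant (-1.06), D17H6S56E-5 (-0.94) and Tcf19 (-0.92). Of 12167 genes, 6 were at least 2-fold higher and 4 at least 2-fold lower. Under quantile normalization these counts were 5 and 6. At 1.5-fold, 68 were higher and 115 lower. Gm7265 (1.02) completes the 6 higher genes and was named after its value was seen.

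All 39 mitosis genes were lower with citalopram at day 7, 25 of them by at least 1.5-fold (median -0.62; matched range -0.07 to 0.08). Besides Cenpa these included the mitotic kinase genes Pbk (-0.91) and Bub1 (-0.80) and Hmmr (-0.80). All 34 genes of DNA replication and S phase were lower (median -0.38), among them thymidine kinase (Tk1, -0.74), the replication factor C subunits Rfc4 (-0.65) and Rfc3 (-0.51), and the DNA polymerase gene Pola1 (-0.39). Genes of cholesterol synthesis and uptake were lower in 20 of 21 (median -0.34), with Idi1 at -0.69 and Fdft1, squalene synthase, at -0.54. Lists for ER chaperones (median -0.17, 19 of 24 lower), collagen processing enzymes (-0.19, 14 of 15 lower), osteoclast-regulating factors (-0.14, 12 of 12 lower), fatty acid synthesis (-0.13, 14 of 18 lower), cytokines, chemokines and inflammation (-0.11, 26 of 30 lower) and interferon response (-0.10, 20 of 27 lower) stood below their matched ranges, as did myogenic markers (-0.15, 8 of 9 lower). Examples are the chaperone gene Sdf2l1 (-0.50) and the interferon-induced Rtp4 (-0.73). Only 20 of the 30 cytokine list members, 18 of the 27 interferon genes and 6 of the 9 myogenic markers reached the floor on any array. Higher were targets of p53 and growth arrest genes (median 0.16, 19 of 26), with Gadd45a at 0.63 and Trp53inp1 at 0.62, and the NRF2 list (0.13, 18 of 21), with Osgin1 at 0.75. Between the 2 untreated arrays the NRF2 median differed by about as much (0.12). The p53 targets Cdkn1a and Bax were not measured. Over both days, limma adjusted over the p53 list alone called 0 of 23 genes (smallest adjusted p 0.0941). The ATF4 and amino acid response list was also higher (0.09, 20 of 33), with the stress-induced Nupr1 at 0.74 and Atf3 at 0.71, but it fell within the matched range under quantile normalization and cyclic loess. In all, 3 of 46 lists stood above and 10 below.

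At both days, 5 genes were at least 1.5-fold higher with citalopram: Fosb (0.91 and 1.38), Hmox1 (1.03 and 0.63), Irs1 (0.66 and 1.15), Cacna1g, which encodes a T-type calcium channel (0.77 and 0.75), and Gstm1 (0.67 and 0.75). For Irs1 this rests on the brighter of its 2 features, which ranged from 0.24 to 0.66 at day 3. The 3 genes at least 1.5-fold lower at both days were H2ac4 (-0.83 and -0.71), Shcbp1 (-0.73 and -0.68) and Cmbl, a hydrolase gene (-0.63 and -0.67). Independent lists would share 0.293 higher genes (from 53 and 66) and 0.340 lower genes (from 36 and 113) among the 11952 genes above the floor at both days. No gene passed 2-fold at both days, and 0 genes passed 1.5-fold in opposite directions. Across these genes, which are not independent replicates, the changes at the 2 days correlated with r = 0.181 and rho = 0.136, and 53.2% had the same sign. The mean of the 2 changes reached 1.5-fold for 20 genes in the higher and 15 in the lower direction, against 3 and 6 for their difference divided by 2.

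Over both days, limma called 0 of 12415 genes for citalopram on the deposited values (smallest adjusted p 0.249), with 661 genes higher and 458 lower at an unadjusted p under 0.05. This count depended on the scaling: limma called 139 genes after quantile normalization (52 higher and 87 lower, with 17 mitosis and 4 S-phase genes among the lower and 3 NRF2 genes among the higher), 40 after cyclic loess (18 higher, 22 lower) and 6 after quantile normalization over named features. It was 0 with a trend and without a floor. It was also 0 with treatment alone, a fit with a smallest adjusted p of 1.00, and with an array left out of that fit; the additive fit allows no array to be left out. Adjusted over the list alone, limma called 37 of 39 mitosis genes lower (smallest adjusted p 0.00840), 6 of 34 S-phase genes lower, 5 of 21 NRF2 genes higher (0.00149) and 4 of 25 immediate early genes higher (0.000501), against 0 in each list over all genes. Members of a list share the same arrays and can be co-regulated, so these are not counts of separate findings. For immediate early genes the examples are Fosb, Nr4a1 (0.50 and 0.57), Klf4 (0.33 and 0.65) and Nr4a3 (0.35 and 0.38). Adjusted over the list alone, limma called 0 of 14 osteoblast differentiation genes and 0 of 20 cholesterol genes, whose opposite changes at the 2 days cancel in this fit.

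**Figure D2:**
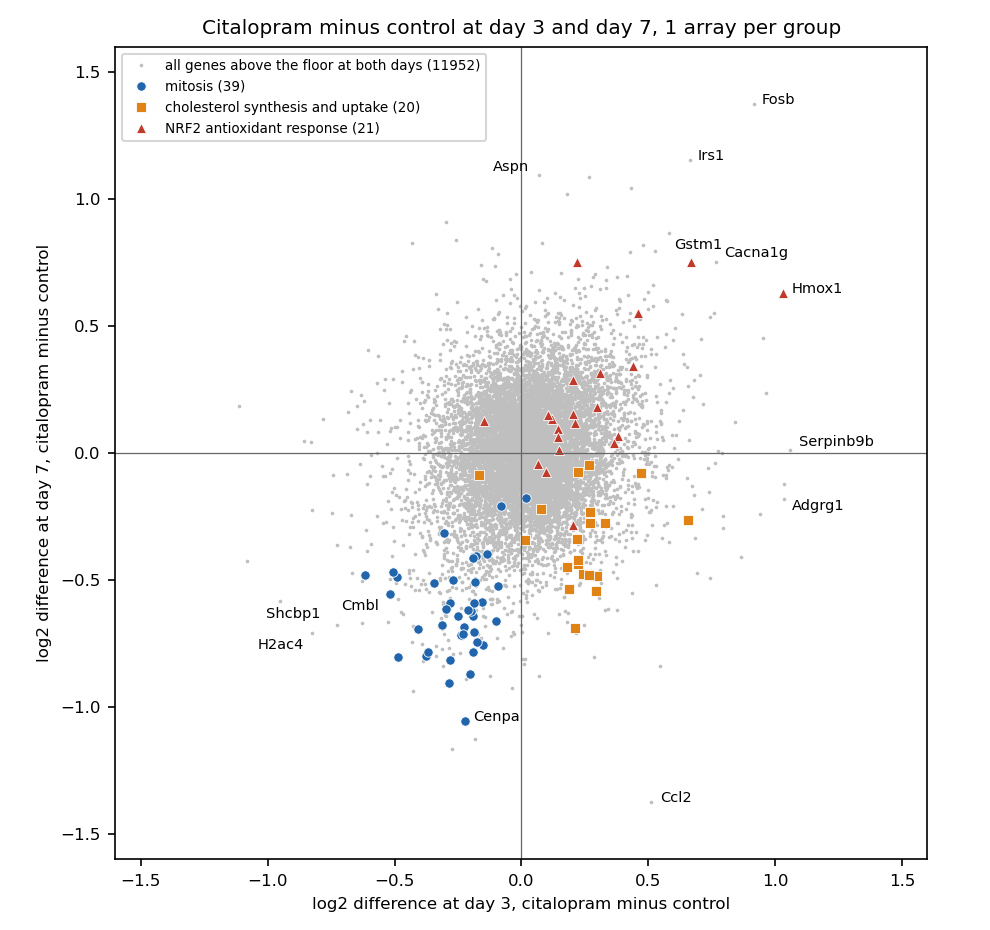
Log2 difference, citalopram minus control, of each of 11952 genes at day 3 (horizontal) and day 7 (vertical), with members of 3 gene lists above the floor drawn in colour. Fosb (0.91 and 1.38) ranks first among genes higher at both days by the smaller of its 2 changes, mitosis genes lie to the lower left, and cholesterol genes lie to the lower right, higher at day 3 and lower at day 7.

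The citalopram change differed in direction between the days for genes of cholesterol synthesis and uptake, of which 19 were higher at day 3 and lower at day 7. Idi1 went from 0.21 to -0.69, Mvk, mevalonate kinase, from 0.19 to -0.54, Fdps from 0.30 to -0.48 and Hsd17b7 from 0.66 to -0.26. The chemokine genes Ccl2 (0.51 and -1.38) and Ccl7 (0.55 and -0.84), Idh1, a cytosolic source of NADPH (0.74 and -0.49), Adgrg1 (1.03 and -0.18) and Fabp7 (0.94 and -0.24) had the most negative differences between the days. Phxr4 (-0.26 and 0.84), Aspn (0.07 and 1.09), Hoatz (-0.34 and 0.63), Thap2 (-0.56 and 0.38) and Thoc2l (-0.12 and 0.81) had the most positive. By 2-fold, 6 genes had a higher and 14 a lower change at day 7 than at day 3. These differences were not tested, since no group has a replicate. The cholesterol list also stood above its matched range between the 2 untreated arrays, by 0.20 at day 7 against day 3.

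Osteoblast genes differed little between citalopram and control, with 0 of 18 measured members of the differentiation list past 1.5-fold at either day. At day 3, 12 of 18 were higher (median 0.14; matched range -0.05 to 0.11), among them Sp7, the osterix gene (0.46), Dlx5, a homeobox regulator of bone formation (0.42), Bmp4 (0.31) and the type I collagen genes Col1a1 (0.25) and Col1a2 (0.20). At day 7 the list lay within its matched range, 8 of 18 being higher, with Dlx5 at 0.23, Sp7 at 0.08 and Col1a1 at 0.04. Of all 18565 protein-coding genes, counted without the floor, 11095 were higher with citalopram at day 3 and 8375 at day 7. Osteomodulin (Omd) was at -0.14 and then 0.47. Sparc, the osteonectin gene, was bright on every array (13.8 to 14.1), whereas alkaline phosphatase (Alpl) lay near the floor (5.93 to 6.09) and Ibsp, Phex, Mepe and Bmp2 lay below it. The mineralisation and phosphate handling list followed the same course, with 10 of 12 higher at day 3 (median 0.18) and a median of -0.09 within its matched range at day 7; Slc20a1, a phosphate transporter gene, was at 0.57 and -0.10.

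**Figure D3:**
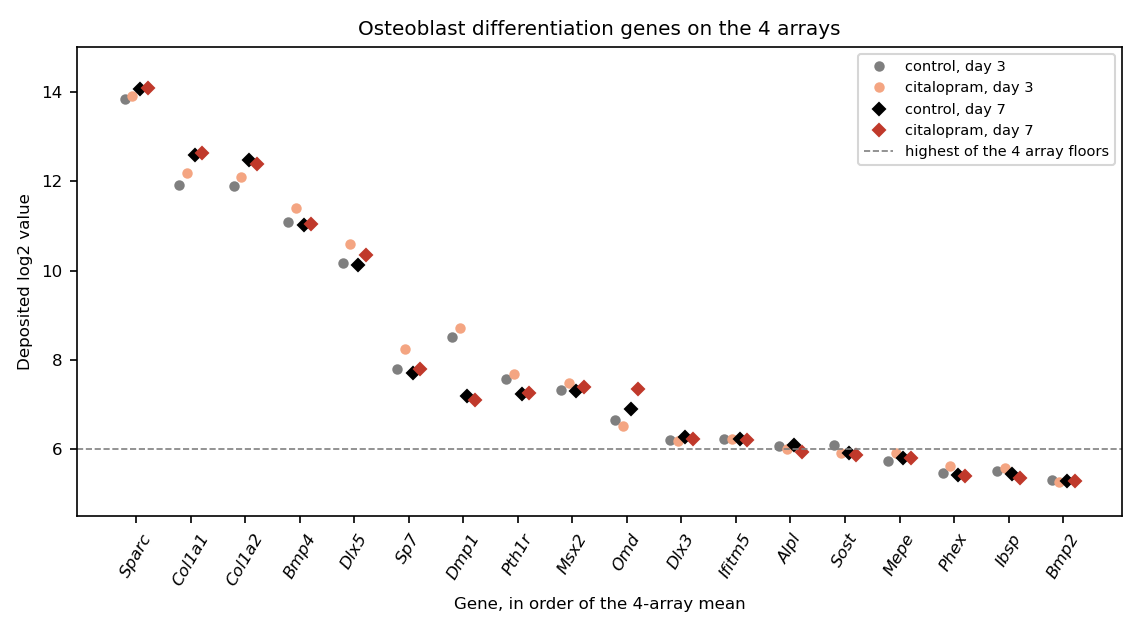
Deposited log2 values of the 18 measured osteoblast differentiation genes on the 4 arrays, 1 point per array, in order of mean level; the dashed line marks the highest of the 4 array floors (6.01). Dmp1 is lower at day 7 than at day 3 in both treatments (by -1.32 in control and -1.61 with citalopram), and Alpl lies near the floor on every array (5.93 to 6.09).

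Of the genes for serotonin and monoamine handling, 6 of 23 reached the floor. Slc6a4, which encodes the serotonin transporter that citalopram blocks, lay below the floor on every array (5.38 to 5.51). Maoa, monoamine oxidase A, was the brightest, at 9.17 in control and 9.24 with citalopram at day 3, and at 9.30 and 9.62 at day 7. Serotonin receptor genes were dim, with Htr1b between 5.97 and 6.00, Htr2a between 5.81 and 6.08 and Htr2b between 5.30 and 5.50. The list median was 0.05 at day 3 and -0.08 at day 7, within the matched ranges, and limma called 0 of 6 members adjusted over the list alone and 0 over all genes.

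More genes differed between day 7 and day 3 than between citalopram and control at either day: in control, 32 genes were at least 2-fold higher and 16 lower at day 7 than at day 3, of 12201. Counted without the floor, 10 protein-coding genes were 2-fold higher and 16 lower. A further 17 of the higher genes were small nucleolar RNA genes, whose Snor symbols the naming rule leaves out. Vaultrc5, a vault RNA, rose (2.70 in control and 3.00 with citalopram; limma's adjusted p for day 7.47e-05), as did Cdsn, the corneodesmosin gene (1.65 and 1.28; 0.00144), Serpinb1a (1.33 and 1.09; 0.00227), Hspg2, which encodes the basement membrane proteoglycan perlecan (1.34 and 0.81; 0.00842), and the cartilage collagen gene Col2a1 (1.22 and 0.49; 0.0397). Cemip, a hyaluronan-degrading protein gene, was higher by 1.26 and 0.37 without passing limma's threshold (adjusted p 0.0613). Nrep fell (-1.59 and -1.59; limma's adjusted p 0.000551), as did Fam110c (-1.49 and -1.37; 0.000706), Dmp1, a matrix protein gene of osteocytes (-1.32 and -1.61; 0.00111), Nipa1, a magnesium transporter gene (-1.31 and -1.22; 0.00144), Ctsw (-1.53 and -1.16; 0.0022) and the cardiac troponin gene Tnnt2 (-1.46 and -1.09; 0.00228). Fgf2 fell too (-0.93 and -1.18; 0.00398), with Vegfa (-0.66 and -0.69; 0.0155) and Tnfrsf11b, the osteoprotegerin gene (-0.63 and -1.18; 0.0175), whereas Adamts5 (1.09 and 0.64; 0.0153) and Col1a1 (0.68 and 0.47; 0.039) rose.

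In control, 7 lists stood above their matched ranges at day 7: cholesterol synthesis and uptake (median 0.20, 16 of 21 higher), fatty acid synthesis (0.16), actin cytoskeleton, SRF and YAP targets (0.13), NRF2 antioxidant response (0.12), interferon response (0.11), Wnt signalling (0.10) and drug metabolism (0.09). Idi1 was higher by 0.45, the fatty acid synthase gene Fasn by 0.46 and Irf9 by 0.71, while Nqo1 rose (0.59; limma's adjusted p for day over both treatments 0.039). Macrophage markers (-0.12, 5 of 9 lower) and chondrocyte markers (-0.08, 10 of 14 lower) stood below, but both lay within their ranges by the mean, with members above the floor and against unmatched lists, and the chondrocyte list also did under the 3 scalings. For the day effect over both treatments, adjusted over the list alone, limma called 5 interferon genes higher, against 1 over all genes, 3 osteoblast differentiation genes higher and 2 lower (1 and 1 over all genes), 4 Wnt genes higher and 2 lower (3 and 0), 4 matrix protease genes higher and 4 lower (1 and 2), and 0 cholesterol genes.

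With citalopram, 53 genes were at least 2-fold higher and 46 lower at day 7 than at day 3, of 12187; under quantile normalization these counts were 48 and 69. Counted without the floor, 11 protein-coding genes and 26 small nucleolar RNA genes were 2-fold higher. Besides Vaultrc5, the highest were Malat1, a nuclear long non-coding RNA (2.05, against 1.17 in control), Scarna17 (1.76 and 1.05), Gas5, a host gene of small nucleolar RNAs (1.52 and 0.92; its features ranged from 0.67 to 1.52 with citalopram and from -0.16 to 0.92 in control), Ahnak2 (1.44 and 1.03) and Lncpint (1.41 and 0.95). The lowest were Havcr2, an immune receptor gene (-2.20, against -1.25 in control), Srpx2 (-1.75 and -1.16), Cotl1, an actin-binding protein gene (-1.73), C1qtnf3 (-1.68 and -1.07), the junction gene Jam2 (-1.68 and -0.99) and the semaphorin gene Sema7a (-1.63 and -1.16). Mitosis (median -0.35, 34 of 39 lower), DNA replication and S phase (-0.29), cholesterol synthesis and uptake (-0.32, 19 of 21 lower), osteoclast-regulating factors (-0.30, 12 of 12 lower), lysosome (-0.22), collagen processing enzymes (-0.22), ER chaperones (-0.19) and cytokines, chemokines and inflammation (-0.15) stood below their matched ranges. Targets of p53 (0.11), immediate early genes (0.11) and the ATF4 list (0.09) stood above, but under quantile normalization the last 2 medians were -0.03 and -0.01.

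Across both treatments, limma called 348 of 12415 genes for day on the deposited values, 163 higher and 185 lower at day 7, and 2496 at an unadjusted p under 0.05. The time changes of the 2 treatments, which share no array, correlated across 11977 genes with r = 0.566 and rho = 0.459. Scaling moved the balance: limma called 459 higher and 1085 lower after quantile normalization, 1018 in all after cyclic loess, and 409 and 413 after quantile normalization over named features, and all 348 genes were among the calls of each. Fitted with day alone, limma called 68 genes, and leaving out an array from that fit gave 29 (without citalopram at day 3), 43 (without control at day 3), 211 (without citalopram at day 7) or 967 (without control at day 7). Each day may form its own batch of cultures and arrays, so time and batch cannot be told apart.

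Most lists of markers of other cell types were dim, the smooth muscle list being the brightest (median level 9.12). Medians of the adipocyte list were 0.00 at day 3 and -0.11 at day 7, with citalopram against control, and those of the chondrocyte list were 0.01 and -0.04, all within the matched ranges. Sox9, a transcription factor of cartilage, was at 0.41 and 0.28. Adjusted over the list alone, limma called 2 chondrocyte markers higher and 1 lower for citalopram, against 0 over all genes. Lyz2, a lysozyme gene of macrophages, was higher by 0.57 and 0.47, whereas the macrophage list had medians of 0.00 and 0.04. Only 3 of the 9 macrophage markers reached the floor. Of these, limma adjusted over the list alone called 1 higher for citalopram (adjusted p 0.00306), against 0 over all genes. Osteoblast markers (0.15 and -0.02, 4 genes) and osteocyte markers (0.17 and -0.04, 6 genes) lay within their ranges. Housekeeping genes had medians of 0.07 and -0.01, with Actb at 0.26 and 0.01.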

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

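Among the tests below, what the scaling tests would show was written before their results were seen, but the scaling over named features, the snoRNA class and all other tests were chosen only after the data were seen.

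Genes of cholesterol synthesis and uptake stood apart in opposite directions at the 2 days. Their median citalopram change at day 7 lay below that at day 3 by -0.56. Taken as change over time, their median with citalopram lay below that in control by -0.51. For each gene these are the same difference from the same arrays, so the 2 values are not separate evidence. They are unequal only because medians were subtracted. Under 3 other scalings the list's citalopram median at each day stayed within 0.01 percentile points of the ends of the matched random lists. Those lists are rescaled along with the cholesterol list, so this percentile could hardly move and is a weak test of scaling. The scalings moved the median of all genes by at most 0.048 log2 units. A shift of all genes of that size is too small to give list medians of 0.22 and -0.34. A loss of messenger RNA bound to the endoplasmic reticulum would spare the 6 enzymes of the list made in the cytosol. All 6 were lower at day 7 (median -0.46), which argues against such a loss as the cause for the list as a whole. These 6 belong to the list, of which 20 of 21 members were lower, so their values restate the pattern and are not a separate test. What stays open is variation between cultures or sampling times, because the list also stood apart between the 2 untreated arrays (0.20), and an effect of citalopram that turns with time. The difference between the days was not tested, since no group has a replicate.

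Fatty acid synthesis genes likewise stood above their matched range at day 3 and below it at day 7, a difference of medians of -0.25 that was not tested. This list, too, stood above its matched range between the 2 untreated arrays, by 0.16 at day 7 against day 3.

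Features that the annotation leaves unnamed, used in no comparison of genes, held many 2-fold differences that involve the citalopram array at day 7: 223 of 12146 were higher with citalopram than in control (39 lower), and with citalopram 1013 were higher at day 7 than at day 3 (29 lower). At day 3, 92 were higher and 107 lower with citalopram, and over time in control 332 were higher and 50 lower. Small nucleolar RNA genes were also higher at day 7, and for these scaling is argued against as the whole cause, since their lowest median over 4 scalings and both treatments was 0.64. The unnamed features were not tested under other scalings, so scaling stays open for them, and what they measure was not worked out. A difference in RNA extraction, labelling or hybridisation between the days stays open for the snoRNAs, whose median was 0.99 with citalopram too, and cannot be told apart from a biological change over time because each day may be its own batch.

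Mitosis and S-phase genes were lower with citalopram at both days in separate pairs of arrays. Under 3 scalings both lists stayed below all or nearly all matched random lists (highest percentile 0.0). The matched lists are rescaled along with these lists, so this percentile could hardly move and is a weak test of scaling. The scalings moved the median of all genes by at most 0.048 log2 units. A shift of all genes of that size is too small to give mitosis medians of -0.23 and -0.62. A shift of RNA composition towards snoRNAs at day 3 is argued against by their median of -0.20, and a general loss of messenger RNA at day 7 by oxidative phosphorylation genes, whose lower quartile was -0.16 against a mitosis median of -0.62. Fewer dividing cells under citalopram is a candidate explanation that was not tested. The growth state of single cultures apart from the drug also stays open: the mitosis median differed by only 0.0356 between the 2 control arrays, but 1 array per group cannot show how far cultures of 1 treatment differ.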

How the results depend on the processing

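The added scaling (quantile normalization over named features) and the cyclic loess scaling of limma were chosen after the data were seen; all other settings were fixed beforehand. Counting list comparisons once under each alternative, 1140 medians kept their side and direction, 35 came to stand apart, 30 no longer did and 5 reversed. Those that kept their side include comparisons that never stood apart. Fewer than the 184 list comparisons entered this count under each alternative. On the deposited values, the lists standing above and below numbered 12 and 5 at day 3 and 3 and 10 at day 7. Over time they numbered 7 and 2 in control and 3 and 8 with citalopram. Changes of named genes were counted once each under cyclic loess, quantile normalization and the mean of a gene's features. Of these counts, 348 kept their side and 6 no longer passed, with 0 reversed. The scalings moved the median of all genes by under 0.05 log2 units.

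At 1.5-fold in place of 2-fold, counts of higher and lower genes were 61 and 37 at day 3, 68 and 115 at day 7, 142 and 138 over time in control, 244 and 342 over time with citalopram, and 139 and 212 for the difference between days. At 2-fold, 0 higher and 0 lower genes were shared by both days. With the floor at the 60th percentile, day 3 had 3 higher and 1 lower, and the difference between days 2 and 5. The mean of a gene's features left 1 lower gene at day 3.

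limma's citalopram calls went from 0 to 139 under quantile normalization, 40 under cyclic loess and 6 under quantile normalization over named features. The prior degrees of freedom rose with them, from 7.15 to 25.7, 14.9 and 11.1, which lowers p-values for the same changes. Its 348 calls for day were 68 with day alone, 190 without a floor (19938 genes tested), 1544, 1018 and 822 under the 3 scalings, and 29 to 967 with 1 array left out, where the lone array of a day is assumed to vary like the others. With both terms, no array can be left out, as no residual degree of freedom remains.

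Reversed medians were the ATF4 list over time with citalopram (-0.0085 under quantile normalization), immediate early genes in the same comparison (-0.0133 by the mean, -0.031 under quantile normalization), interferon genes at day 3 (0.0260 by the mean) and chondrocyte markers over time in control (0.00649 by the mean, which Col2a1 at 1.22 raises). Lists standing below at day 3 numbered 3 by the mean or with members above the floor, without the interferon list and endothelial markers. Lists standing above at day 7 numbered 5 by the mean or against unmatched lists. Over time in control, lists standing below numbered 1 by the mean and under quantile normalization, cyclic loess and quantile normalization over named features, and 0 above the floor or against unmatched lists. Over time with citalopram, 5 stood above with members above the floor. The cause was not tested unless stated. Members near the floor, such as serotonin receptor genes and most cell type markers, limit what their lists can show.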

Other observations

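The gene classes in the next paragraphs, and their comparison with matched random lists, were chosen only after their values were seen.

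Replication-dependent histone genes were lower with citalopram at both days, in 25 of 26 genes at each (median -0.32 at day 3 and -0.27 at day 7; matched ranges -0.03 to 0.11 and -0.08 to 0.07). They did not stand apart over time, with medians of -0.02 in control and -0.01 with citalopram. Their copies are near-identical, so single members are uncertain. Genes of cytosolic ribosomal proteins (55) stood apart by small amounts, with medians of 0.01 at day 3 (matched range 0.02 to 0.10) and 0.05 at day 7 (-0.08 to 0.02). Over time their medians were 0.10 in control (-0.04 to 0.08) and 0.10 with citalopram (-0.13 to 0.01).

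Small nucleolar RNA genes, which guide the modification of ribosomal RNA, were higher at day 7 than at day 3 in 50 of 54 genes in control (median 0.67, 17 by at least 2-fold) and in 52 of 54 with citalopram (0.99, 26 by at least 2-fold). Between treatments they were lower with citalopram at day 3 (-0.20, 46 of 54) and slightly higher at day 7 (0.07, 35 of 54).

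The single genes that follow are among the members with the largest absolute mean citalopram change of lists that stood within their matched ranges at both days. Among lysosome genes, Gpnmb, a glycoprotein gene, was higher with citalopram by 0.74 and 0.54, while the list medians were 0.10 and -0.06. In the list of fatty acid oxidation, medians 0.01 and 0.04, Cpt1a, the carnitine palmitoyltransferase of mitochondrial import, was higher by 0.43 and 0.38 and Plin2, a lipid droplet coat gene, by 0.34 and 0.35. Extracellular matrix genes had medians of 0.04 and -0.03, with Mfap5 at 0.60 and 0.49, Ogn at 0.28 and 0.69 and tenascin C (Tnc) at -0.12 and -0.60. Cyp1b1, of the drug metabolism list (medians 0.10 and -0.04), was higher by 0.53 and 0.34. limma's adjusted p for citalopram over all genes lay between 0.312 and 0.479 for these genes.

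Heat shock genes (medians -0.02 and 0.06), autophagy genes (0.07 and 0.03), apoptosis genes (0.07 and 0.01) and aminoacyl-tRNA synthetase genes (0.01 and 0.04) lay within their matched ranges at both days. Of the metallothioneins, Mt1 was higher by 0.40 and 0.24 and Mt2 by 0.40 and 0.14.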
